A study of Mus musculus with 14 samples.

How the data were processed

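Total RNA of mouse retinas (C57BL/6) at E14.5 was sequenced in 14 samples: 3 wild types and 3 knockouts of the line labelled SE, and 4 wild types and 4 knockouts of the line labelled EN1. Per the labels' protocols, RNA came from fresh retinas by a column kit and libraries were made with standard Illumina reagents. The values are deposited counts of reads per gene, raw and unnormalized, in 1 table per line. Per the submitters' processing notes, Trimmomatic 0.38, STAR and HTSeq 0.11.2 were used, with the mm10 build. The annotation, the strand setting of the counting and the version of STAR are not given in the sources used here. Without a strand setting, reads from a stretch that 2 genes share cannot be told apart, and reads of near-identical copies such as Eno1 and Eno1b may be dropped or placed on either copy. Gene names turned into dates, as a spreadsheet does, stand for 27 entries of the SE line; they stayed in the SE test and entered no comparison with the EN1 line and no list.

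Samples were grouped by genotype and line from their labels, and replicates are numbered as the labels number them. The labels do not say that replicates are separate animals, so that p-values measure only the spread between these samples, which may be technical. The 2 tables' columns carry genotype and replicate number, and were given to the line that each table names. Pairs of replicates differed by far more than sampling noise, and none was treated as 1 library. EN1 wild types 1 and 4 lay closer to each other, as did 2 and 3, than the other wild-type pairs of that line. Chi-square per degree of freedom was 26.7 and 28.1 in these pairs, against 97.1 to 134 in the others. The labels give no batch. Whether samples with the same number deviate together was checked, and the numbers were not used as pairs.

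Each line was tested alone with edgeR 4.0.16 in R 4.3.3: genes were filtered with filterByExpr by group, scaled with TMM, fitted with glmQLFit (robust) and tested with glmQLFTest. The difference between the knockout effects was tested as an interaction over all 14 libraries and the genes present in both tables. Adjusted p is by Benjamini-Hochberg, and genes with an adjusted p under 0.05 were called, with no minimum fold. The standard error of a log2 fold change was taken from the quasi-likelihood F statistic. CPM are taken after TMM scaling, given as mean ± SD over libraries. Vsx2 was also compared with an exact two-sided permutation test of log2 CPM. Libraries held 18.6 to 34.3 M counts, and genes below 1 CPM were measured with little precision.

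The lists of genes, 28 in all, were fixed before the data were examined, as were the tests, the naming rule and the main set of alternatives. They cover retinal progenitors, neurogenic progenitors, ganglion cells, photoreceptors, amacrine and horizontal cells, bipolar cells, melanin genes, other RPE genes, the ciliary margin, retinal patterning, DNA replication, mitosis, G1 cyclins and cell cycle inhibitors, targets of FGF, hedgehog, Wnt and p53 signalling, hypoxia and glycolysis, immediate early and stress genes, lens, mesenchyme around the eye, red blood cells, endothelium, macrophages, surface ectoderm, mitochondrially encoded genes, sex-linked genes and genes flanking Vsx2. Of these 25 were tested as lists with camera (limma 3.58.1, preset correlation 0.01, at least 3 tested genes); sex-linked and flanking genes were not planned as list tests, and no gene of the 13 mitochondrially encoded ones was tested. List tests of the difference between the lines were added after the plan. Each list was also counted by its called genes, over all genes and adjusted over the list alone, and tested with a correlation estimated from the data and with fry. A list test compares a list with the other genes, and fry asks only whether its genes move one way.

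Genes to be named were chosen by a fixed rule, and the text gives part of those chosen from the lists: Vsx2 first; per line up to 8 rises and 8 falls by size among called genes with at least 5 CPM in the higher group, no overlap of libraries and a name that is not a predicted-gene name; up to 4 called genes per list, by adjusted p, or 2 by p where none was called; called genes flanking Vsx2 with Lin52 and Abcd4; up to 5 genes per direction for the difference; and genes called in both lines. Gm7120, Pmel, Dct, Slc6a9, Cenpf, Eno1 and Cryaa, and the ribosomal protein genes as a group, fall outside the rule and were named after their values were seen. Coordinates are those of GENCODE M21 on mm10: of 24436 gene names deposited, 23334 matched 1 gene by name, 667 through a RefSeq synonym, and 435 did not match 1 gene.

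Recovery was tried on simulated counts with the SE libraries' means and sizes (15203 genes). The test recovered 11.9% of genes changed 1.5-fold, 43.3% of genes changed 2-fold and 81.8% of genes changed 4-fold, with 7 false calls of 98. For the EN1 libraries (14676 genes) it recovered 11.9, 62.7 and 93.9%, with 8 false calls of 120. For the difference (15564 genes) it recovered 1.49, 11.9 and 57.6%, with 2 of 49. In each, 67, 67 and 66 genes were changed at these folds. Genes were drawn independently, without the length and GC trends that the real libraries share. The real SE test called 5 genes, and with fewer calls the adjusted threshold is stricter. The rates may therefore overstate recovery in the SE line.

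Other settings fixed beforehand were DESeq2's size factors in edgeR, the Wald test of DESeq2 1.42.0, no low-count filter beyond 1 count, a filter of 1 CPM, the replicate number as a block, no robust fit, a test against a fold of 1.2, both lines in one fit, leaving out each library in turn, an estimated correlation and fry. Chosen after the data were examined were offsets that remove each library's trend on transcript length or GC content (lowess, span 0.3), DESeq2 with its independent filter on mean counts off, a term for the number of genes with counts in the SE line, and, in the EN1 line, fits without wild types 2 and 3, without wild types 1 and 4, without the 3 libraries with the most lens transcripts (wild type 4 and knockouts 2 and 3), and with a term for the lens level. Every split of the libraries of a line into groups of the same sizes was tested (10 in the SE line and 35 in the EN1 line), and 59 random regroupings were drawn for the difference. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.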

Results

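RNA sequencing was carried out on mouse retinas at E14.5 from 2 knockout lines of regulatory DNA of Vsx2, a homeobox gene of retinal progenitors and bipolar cells. In the line labelled SE, for the Vsx2 super-enhancer, 3 wild-type and 3 knockout samples were sequenced. In the line labelled EN1, whose extent the labels do not give, 4 wild-type and 4 knockout samples were sequenced. Libraries held 20.5 to 34.3 M counts in the SE line and 18.6 to 24.9 M in the EN1 line. The ribosomal RNA precursor Rn45s took 0.265 to 1.37% of counts in the SE libraries and 5.22 to 9.32% in the EN1 libraries. SE wild types 1 and 2 and SE knockout 1 had 19524 to 19956 genes with counts, against 17057 to 17278 in SE wild type 3 and SE knockouts 2 and 3. The comparisons ask which transcripts differ in the retina when either region is missing, and whether the 2 deletions differ in effect.

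Vsx2 transcripts were lower in the knockouts of both lines, and no knockout library reached the level of a wild type. Vsx2 lies on chromosome 12 of mm10 from 84569762 to 84595457. In the SE line it averaged 414.4 ± 38.9 CPM (scaled counts) in wild types and 209.1 ± 15.8 in knockouts (SD, n = 3 each), or 50.5% of wild type. Single SE libraries ranged from 383.8 to 458.2 CPM in wild types and from 191 to 220.3 in knockouts. In the EN1 line Vsx2 averaged 644.7 ± 92.3 CPM in wild types and 220.8 ± 20.9 in knockouts (SD, n = 4 each), or 34.2% of wild type. Single EN1 libraries ranged from 567 to 778.1 CPM in wild types and from 193.4 to 244.2 in knockouts. The log2 fold change was -0.99 (SE 0.135, edgeR adjusted p = 0.044) in the SE line and -1.55 (SE 0.127, adjusted p = 9.4e-05) in the EN1 line. Two-sided exact permutation tests gave p = 0.1 for the SE line, the smallest that 3 against 3 allows, and p = 0.0286 for the EN1 line, also the smallest possible. The SE knockout effect was 0.57 log2 units smaller than the EN1 one (SE 0.19, edgeR unadjusted p = 0.00922). Adjusted over all genes this difference did not pass (adjusted p = 0.086), but it did with DESeq2 (0.0259) and with the GC trend removed (0.0277). Knockout levels were close in the 2 lines (209.1 and 220.8 CPM), while wild types differed (414.4 and 644.7), each line scaled alone. A smaller SE effect and a difference between the lines' wild types cannot be told apart here. The SE call of Vsx2 ended without any one of the 6 libraries: the adjusted p was 0.256, 0.164 and 0.208 without wild types 1, 2 and 3, and 0.0924, 0.298 and 0.0532 without knockouts 1, 2 and 3. It also ended with another scaling (0.0546), with the replicate number as a block (0.066) and without the robust fit (0.0757). The same held against a fold of 1.2 (0.129) and with the GC trend removed (0.0867). The SE call of Vsx2 held with DESeq2 (adjusted p = 3.85e-08, and 8.05e-08 with its filter on mean counts off). In edgeR it held without a low-count filter (0.00015) and in one fit of both lines (0.0137). A filter of 1 CPM (0.039), the length trend removed (0.0355) and a term for detected genes (0.0497) also kept it. Through all of these fits the log2 fold change stayed between -1.04 and -0.84.

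**Figure D1:**
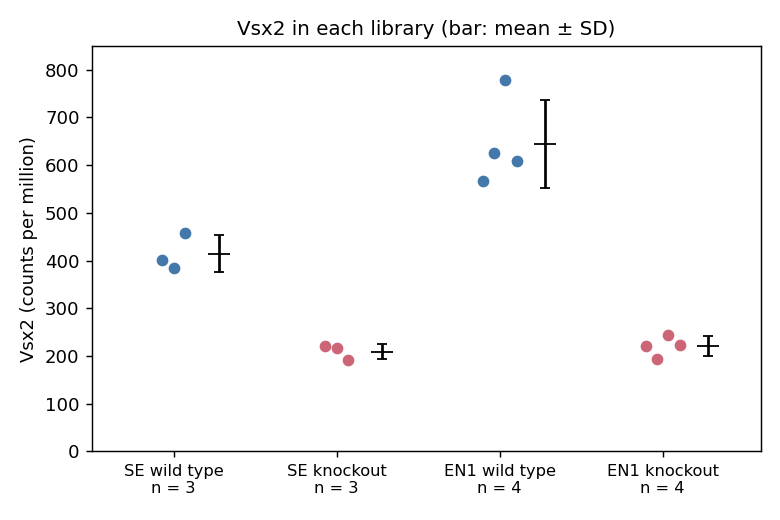
Vsx2 level in CPM in each library of the SE line (n = 3 wild types and 3 knockouts) and the EN1 line (n = 4 and 4); points are libraries and bars the mean with its SD. SE knockouts lie between 191 and 220.3 and EN1 knockouts between 193.4 and 244.2, below every wild type.

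Besides Vsx2, 4 genes changed in the SE knockouts. Eno1b, an enolase gene copy on chromosome 18 (48045335 to 48048412), rose from 1.65 ± 0.928 to 68.9 ± 0.897 CPM, a log2 fold change of 5.37 (SE 0.318, adjusted p = 4.96e-05). Its sequence is close to that of Eno1, which held 0 counts in all 6 SE libraries, so reads of the 2 copies cannot be assigned with certainty. Zfp277, a zinc finger gene on chromosome 12 (40315046 to 40445902), fell from 45.5 ± 3.5 to 11.3 ± 2.65 CPM (log2 fold change -2.01, SE 0.197, adjusted p = 0.00406). Cep128, a centriole gene on chromosome 12 (90998492 to 91384409), rose from 46.0 ± 4.73 to 103.4 ± 3.33 CPM (log2 fold change 1.17, SE 0.137, adjusted p = 0.0166). Gm7120 on chromosome 13 (119488039 to 119611059), a predicted gene outside the naming rule and named after its values were seen, fell from 16.9 ± 1.05 to 4.08 ± 1.08 CPM (log2 fold change -2.05, SE 0.249, adjusted p = 0.0172). Lin52 and Abcd4, the neighbours of Vsx2, had log2 fold changes of 0.03 and -0.22 and did not pass (adjusted p = 0.95 and 0.816). In all, edgeR's quasi-likelihood test called 5 of 15693 genes, 2 higher and 3 lower. At an unadjusted p under 0.05 there were 1943 genes against 785 expected by chance, and 1205 with the gene length trend removed. DESeq2 called 339, 253 higher and 86 lower. DESeq2's filter set aside 13811 genes with a mean under 506 counts, Gm7120 among them, and with that filter off it called 176, Gm7120 included, 118 higher and 58 lower. Without a low-count filter edgeR called 83, 51 higher and 32 lower. The call of Cep128 ended without SE wild type 1, 2 or 3 (adjusted p = 0.0958, 0.139 and 0.0761) or without SE knockout 2 (0.126), and in a fit of both lines together (0.114). The call of Gm7120 ended without SE wild type 1, 2 or 3 (0.145, 0.149 and 0.0761) or SE knockout 2 (0.133).

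No gene of the retinal cell type lists passed edgeR's test in the SE knockouts. The melanin genes had a median log2 fold change of -0.23, the other genes of the retinal pigment epithelium (RPE) 0.33, and the retinal progenitor genes 0.09. Without 1 library these medians ran from -0.66 to 0.20, from 0.09 to 0.45 and from -0.03 to 0.15, in that order. Mitf, the transcription factor of pigment cells, was at 8.1 ± 0.776 CPM in SE wild types and 19.9 ± 11.5 in SE knockouts (log2 fold change 1.3, adjusted p = 0.224; called by DESeq2 only with its filter off, 0.0356). DESeq2 also called Nefm, a neurofilament gene of the ganglion cell list (0.02), Aldh1a3 of the patterning list (0.0275), and the mitosis genes Mki67 (0.00195), Cenpe (0.0196) and Cenpf (0.0274), all higher, and edgeR called Mki67 without a low-count filter (0.0122). Aldh1a3 and Cenpf were not called by DESeq2 with its filter off. Across the other settings the log2 fold change ran from 0.42 to 0.77 for Mki67 and from 0.38 to 0.65 for Cenpe. The mitosis list had a median of -0.01. Fold changes in this line rose with transcript length (Spearman 0.403 across genes), and whether length accounts for these DESeq2 calls was not tested. All 12 genes of neurogenic progenitors had negative log2 fold changes (median -0.25), but the list did not pass (adjusted p = 0.0634). It passed without SE wild type 2 (0.00281) or SE knockout 3 (9.91e-05), and with a term for the number of genes with counts (0.000152). The other RPE list passed without SE wild type 2 (0.0398) or SE knockout 3 (0.0292) and with the gene length trend removed (0.023), against 0.181 here. The ganglion cell list (median 0.16, adjusted p = 0.181) passed without SE wild type 1 (0.00707), SE knockout 1 (0.0367) or SE knockout 3 (0.00242) and with the length trend removed (0.023). The melanin list passed without SE knockout 1 (0.0097), and the photoreceptor and ciliary margin lists without SE knockout 3 (0.0269 and 0.0292). Adjusted over the list alone, 2 ganglion cell genes, 1 of the other RPE genes and 3 mitosis genes were higher, and 2 mitosis genes were lower.

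The glycolysis and hypoxia genes were lower as a list in the SE knockouts (median log2 fold change -0.32, adjusted p = 0.00102). The adjusted p was 0.899 with an estimated correlation and 0.676 with fry. Without 1 library the median of the list ran from -0.445 to -0.134 (adjusted p up to 0.0321). None of its 15 tested genes passed alone in edgeR, and 4 were lower adjusted over the list alone. Ldha, which makes lactate, was at 1192 ± 198 CPM in wild types and 739.2 ± 47 in knockouts (adjusted p = 0.193), and the glycolytic gene Aldoa had a log2 fold change of -0.53 (adjusted p = 0.224). DESeq2 called both lower (0.00307 and 0.0288, Aldoa not with its filter off), and edgeR called Ldha without a low-count filter (0.0254). Lens genes were also lower as a list (median -2.41, adjusted p = 5.13e-05, and adjusted p = 0.899 with an estimated correlation and 0.829 with fry). None of 18 was called by edgeR over all genes and 0 adjusted over the list alone, and DESeq2 with its filter off called 2 lower. Without 1 library the median ran from -4.15 to -0.985. The lens crystallin Cryaa reached 63.93 CPM in SE wild type 1 and between 4.49 and 14.46 in the other wild types, against 0.46 to 14.31 in the knockouts. Transcript length moved with genotype in this line: the correlation across genes of log2 fold change with length was 0.403 (Spearman, genes are not independent replicates). Macrophage, endothelial and red blood cell genes passed as lists only without SE knockout 1 (0.00457, 0.0189 and 0.000216), and surface ectoderm genes only without SE wild type 3 (0.00813). Genes of the mesenchyme around the eye passed without SE wild type 2 (0.00649) or SE knockout 2 (0.00489) and with a term for the number of genes with counts (0.0119). Among 25 lists tested lens and hypoxia genes alone passed here, and the adjusted p of the others ran from 0.0634 to 0.939.

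The EN1 knockouts had far more transcripts of pigment cells and of the margin of the eye cup. All 11 melanin genes tested rose, with a median log2 fold change of 2.89. Pmel, a protein of the melanosome, went from 24.4 ± 12.6 to 209 ± 62.2 CPM, and Dct and Tyrp1, enzymes of melanin synthesis, from 6.75 ± 3.88 to 84.2 ± 16 and from 3.48 ± 1.21 to 32.0 ± 3.66 (SD, n = 4 each). Of 11 other RPE genes 6 rose and none fell: Mitf went from 6.76 ± 2.25 to 119.6 ± 8.3 CPM, and Tfec, a related factor, rose by 4.99 log2 units (SE 0.278). Otx1, an eye cup homeobox gene that is in both the RPE and the ciliary margin list, went from 35.5 ± 12.5 to 223.9 ± 36.3 CPM. Of 10 ciliary margin genes 8 rose, among them Gja1 (log2 fold change 2.31, SE 0.224) and Bmp7 (1.32, SE 0.166), and 1 fell (0 or 1 without 1 library). Of 8 Wnt target genes 6 rose, among them Axin2 (1.29, SE 0.185), which is also a ciliary margin gene, and Dkk1 (2.31, SE 0.331).

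The tests of these lists gave adjusted p = 3.37e-13 for melanin, 6.15e-12 for other RPE, 3.53e-07 for the ciliary margin and 0.0014 for Wnt targets. In that order, the adjusted p was 0.0715, 0.0389, 0.223 and 0.245 with an estimated correlation, so that only the other RPE list kept its call. With fry, which asks only whether a list's genes move one way, it was 0.000231, 3.92e-05, 0.00155 and 0.00352. Adjusted over the list alone, 11, 7, 8 and 6 genes were higher. The Wnt list also ended its call without EN1 wild types 1 and 4 (0.282) and without the 3 libraries highest in lens genes (0.0562).

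Transcripts of neurogenic progenitors and of early neurons were lower in the EN1 knockouts. Of 12 neurogenic genes 10 fell (median log2 fold change -0.79), among them the proneural factors Ascl1, from 143.4 ± 18.5 to 36.2 ± 7.1 CPM, and Neurog2, from 225.5 ± 31 to 101.5 ± 7.14, and the Notch ligand Dll3, which fell by 2.42 log2 units (SE 0.204). Of 16 amacrine and horizontal cell genes 10 fell and Slc6a9, a glycine transporter, rose (median -1.29). Ptf1a, Prdm13 and Lhx1, factors of these cells, fell by 2.53 (SE 0.192), 2.37 (SE 0.136) and 3.26 (SE 0.295) log2 units. Of 16 ganglion cell genes 10 fell (median -1.06), among them Isl2, from 13.5 ± 2.8 to 2.97 ± 0.652 CPM, and Pou4f3 (log2 fold change -2.45, SE 0.315). Of 12 photoreceptor genes 8 fell (median -0.99), among them Otx2, from 133.7 ± 2.54 to 65.7 ± 3.89 CPM, and Prdm1 (-1.22, SE 0.147).

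The tests of these lists gave adjusted p = 1.98e-11 for neurogenic, 4.87e-11 for amacrine and horizontal, 1.19e-08 for ganglion cell and 2.82e-06 for photoreceptor genes. In that order, the adjusted p was 0.0705, 0.0508, 0.231 and 0.0508 with an estimated correlation. With fry it was 0.000157, 0.000231, 0.00584 and 0.000157. Adjusted over the list alone, 11, 10, 11 and 8 genes were lower. The deviation of each EN1 library correlated with GC content across genes, at -0.361 and -0.434 in wild types 1 and 4 and at 0.51 and 0.599 in wild types 2 and 3 (Spearman).

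**Figure D2:**
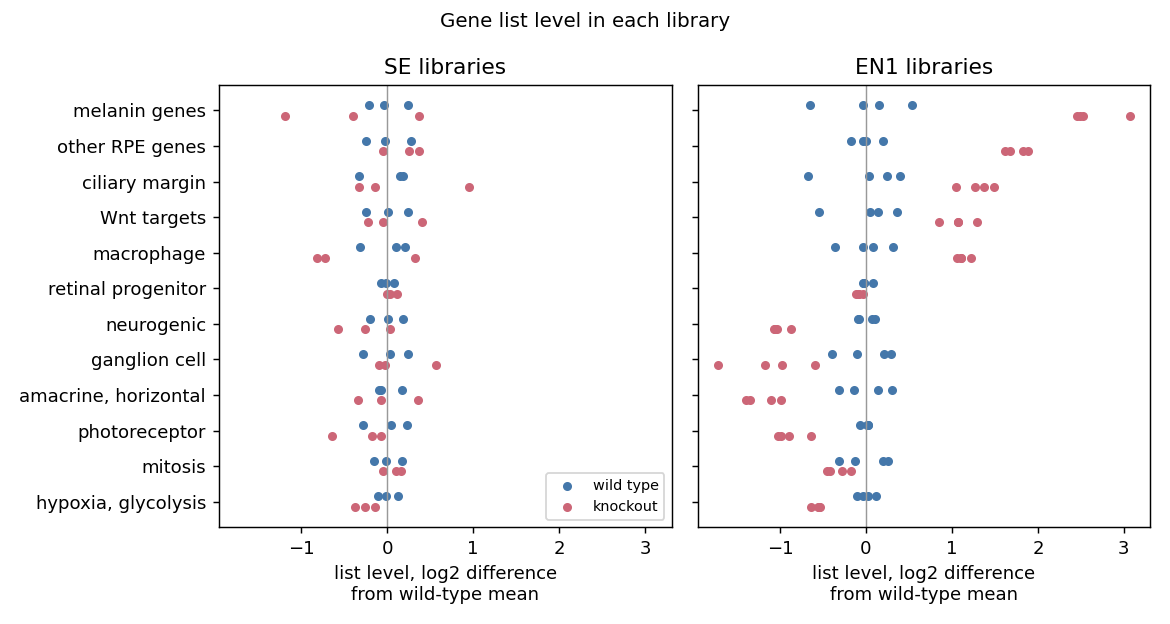
Mean log2 level of 12 gene lists in each library, as the difference from the wild-type mean of its line; points are libraries (SE line, n = 3 per genotype; EN1 line, n = 4 per genotype). EN1 knockouts lie above their wild types for melanin and other RPE genes and below them for neurogenic genes. The median log2 fold changes of the genes were 2.89, 0.85 and -0.79, and their means 2.69, 1.77 and -1.02.

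Retinal progenitor genes went both ways in the EN1 knockouts, with 4 higher and 4 lower of 16 (adjusted p = 0.431; median log2 fold change 0.03, mean -0.08, and a test direction downward). Adjusted over the list alone, 5 were higher and 5 lower. The Notch effector Hes5 fell from 209.5 ± 32 to 70.2 ± 8.42 CPM, Nr2e1 fell by 1.5 log2 units (SE 0.139), and Hmga2 rose by 1.31 (SE 0.114). Of 14 genes that pattern the retina 6 were higher and 5 lower (6 and 6 adjusted over the list alone), and as a list they did not pass (adjusted p = 0.913). Without 1 library 4 to 6 were higher and 3 to 5 lower. Aldh1a1, a retinaldehyde dehydrogenase, went from 472.7 ± 99 to 3221 ± 551 CPM, Tbx5, a T-box factor, rose by 1.52 log2 units (SE 0.136), and Vax1, a homeobox factor, went from 4.45 ± 0.8 to 0.236 ± 0.0674 CPM.

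Mitosis genes fell modestly in the EN1 knockouts, 10 of 20 (13 adjusted over the list alone), with a median log2 fold change of -0.45 (adjusted p = 8.22e-04, and adjusted p = 0.0936 with an estimated correlation). Birc5 went from 79.6 ± 8.22 to 53.6 ± 3.41 CPM and Kif20a from 127.2 ± 10.5 to 88.8 ± 5.62. None of the 20, these 2 included, was called without the 3 libraries highest in lens genes (EN1 wild type 4 and knockouts 2 and 3), where the median was -0.43, and without 1 library 5 to 12 were. Of 22 DNA replication genes 4 fell, with Uhrf1 at -0.8 (SE 0.142), and 1 rose (the same counts adjusted over the list alone). That list had a median of -0.29 (adjusted p = 0.0241, and adjusted p = 0.231 with an estimated correlation) and did not pass without those 3 libraries (0.0622); without 1 library 2 to 8 of its genes fell and 0 or 1 rose. Of 15 hypoxia and glycolysis genes 9 fell and 1 rose (11 and 1 adjusted over the list alone), with a median of -0.64 (adjusted p = 5.44e-06, and adjusted p = 0.0652 with an estimated correlation). Ndrg1 fell from 98 ± 10.2 to 22.9 ± 4.93 CPM and Ldha from 646.8 ± 108 to 298.6 ± 28.2. Without 1 library 6 to 10 genes of that list fell and 0 or 1 rose, and with a term for the lens level 4 fell and 0 rose.

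Macrophage, mesenchyme and lens genes were also higher as lists in the EN1 knockouts. Of 12 macrophage genes 11 rose (11 adjusted over the list alone; median log2 fold change 1.1), among them Csf1r, a growth factor receptor, from 16 ± 5.01 to 38.9 ± 3.01 CPM (list adjusted p = 6.94e-07, and adjusted p = 0.128 with an estimated correlation). Of 12 genes of the mesenchyme around the eye 6 rose (7 adjusted over the list alone; median 1.16), among them Dcn, a matrix proteoglycan, by 2.51 log2 units (SE 0.325); without 1 library 3 to 7 rose. The list passed (adjusted p = 0.0374, and adjusted p = 0.551 with an estimated correlation), but not without EN1 wild type 4 (0.0901), without wild types 1 and 4 (0.492), without the 3 lens-high libraries (0.256), or with the length (0.0589) or GC trend (0.128) removed. Of 22 lens genes 2 rose (2 adjusted over the list alone, and 1 to 14 without 1 library), and the median was 2.02. Foxe3, a lens factor, had 0 counts in wild types 2 and 3 and averaged 16.6 ± 17.1 CPM in knockouts. Cryab, a small heat shock protein, went from 3.57 ± 4.02 to 63.2 ± 57.5 CPM, a call that ended without wild type 1 (0.0614), knockout 3 (0.0543), wild types 2 and 3 (0.196) or 1 and 4 (0.0852), and with a term for the lens level (0.0865). The call of Foxe3 ended without wild types 2 and 3 (0.0978) or 1 and 4 (0.106). The lens list passed (adjusted p = 0.04, and adjusted p = 0.755 with an estimated correlation), but not without wild type 2 (0.0755) or 3 (0.0913), without both (0.39), or without knockout 2 (0.0638), where the median was 0.47. It did not pass with the length (0.0629) or GC trend (0.203) removed, with a term for the lens level (0.514) or with fry (0.172).

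The largest rises in the EN1 knockouts that the naming rule adds were in Fam135b, Tfec, Wnt16, Cdh1, Vmn2r2 and Tacr1. Wnt16, a Wnt ligand, went from 0.659 ± 0.331 to 12.7 ± 1.67 CPM, and Tacr1, a tachykinin receptor, from 2.11 ± 0.967 to 33.9 ± 3.27. Cdh1, the epithelial cadherin, rose by 4.26 log2 units (SE 0.754), a call that ended with a term for the lens level (adjusted p = 0.115) and without wild types 2 and 3 (0.115) or 1 and 4 (0.0848). Among the largest falls, Eomes, a T-box factor, went from 41.1 ± 4.98 to 3.08 ± 1.48 CPM and Ntn1, an axon guidance cue, from 22.4 ± 4.94 to 2.16 ± 0.349. Irx4, Car10, Cacng5, Slc32a1, Onecut3 and Plekhd1 fell by 2.78 to 3.38 log2 units. Near Vsx2, Syndig1l fell by 3.03 log2 units (SE 0.36), Abcd4 rose by 0.56 (SE 0.135, adjusted p = 0.0161) and Aldh6a1 by 0.48 (adjusted p = 0.0447), 3 called of 12 flanking genes. Lin52, on the other side, did not pass (-0.12, adjusted p = 0.521). The Abcd4 call ended without wild type 1 (0.102) or 4 (0.0976), or without knockout 2 (0.0577), 3 (0.124) or 4 (0.111). The Aldh6a1 call ended without wild type 2 (0.0933) or 3 (0.0918), or without knockout 1 (0.108), 2 (0.112), 3 (0.074) or 4 (0.0661).

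In total edgeR called 3593 of 14818 genes in the EN1 line, 1949 higher and 1644 lower, or 54.2% higher. That majority turned with the scaling: under DESeq2's size factors 1612 were higher and 1878 lower, or 46.2% higher. The count was 7658 without EN1 wild types 1 and 4 and 4890 without EN1 wild types 2 and 3. It was 1525 without the 3 lens-high libraries and 1937 with a term for the lens level. Of 25 lists 7 were higher and 7 lower, and 1 passed with an estimated correlation and 16 with fry.

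The 2 knockout effects were compared in one model of all 14 libraries. The difference passed for 1168 of 15826 genes, with the SE effect above the EN1 effect for 565 and below it for 603, or 48.4% above. Under DESeq2's size factors there were 1096 genes, 59.6% of them above. The largest evidence above was for Eno1b (5.67 log2 units, SE 0.433) and Ntn1 (3.58, SE 0.319), then Smoc1, Hs3st4 and Hkdc1. Ntn1 had a log2 fold change of 0.19 in the SE line, where it did not pass, and of -3.38 in the EN1 line. Below were Col9a2, a cartilage collagen, at -2.31 (SE 0.248), Afap1l2, Rab27a, a GTPase of vesicle transport, at -3.03 (SE 0.361), Sned1 and Mterf4. Sned1 and Mterf4 overlap at their ends, and whether the counting used strand is not given, so reads from the shared stretch are uncertain. The count fell to 694 without SE wild type 2, 650 without SE knockout 2, 714 without EN1 knockout 1 and 707 without EN1 knockout 3.

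By list, the SE effect on melanin genes lay below the EN1 effect by a median of 2.95 log2 units (a difference of -2.95, adjusted p = 1.29e-12), with 6 of 11 genes differing (10 adjusted over the list alone). For ganglion cell genes the SE effect lay above it by 1.22 (adjusted p = 2.72e-11), with 6 of 17 differing (12 adjusted over the list alone). For amacrine and horizontal cell genes it lay above by 1.23 (adjusted p = 1.2e-08), with 5 of 16 above and 1 below (9 and 1 adjusted over the list alone). Without 1 library, 5 to 8 melanin genes lay below, 2 to 10 ganglion cell genes above, and 5 to 7 amacrine and horizontal cell genes above with 0 or 1 below. The adjusted p of these 3 lists was 0.051, 0.155 and 0.051 with an estimated correlation. Of 25 lists 13 differed, and none did with an estimated correlation, while 13 did with fry.

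Vsx2 was the only gene called in both lines, against 0.336 genes lower in both expected from independent lists (one-sided Fisher's exact test, p = 0.3). Across 14590 genes tested in both, the log2 fold changes correlated at r = 0.0739 and rho = 0.155 (genes are not independent replicates). DESeq2 called 55 genes in both lines.

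**Figure D3:**
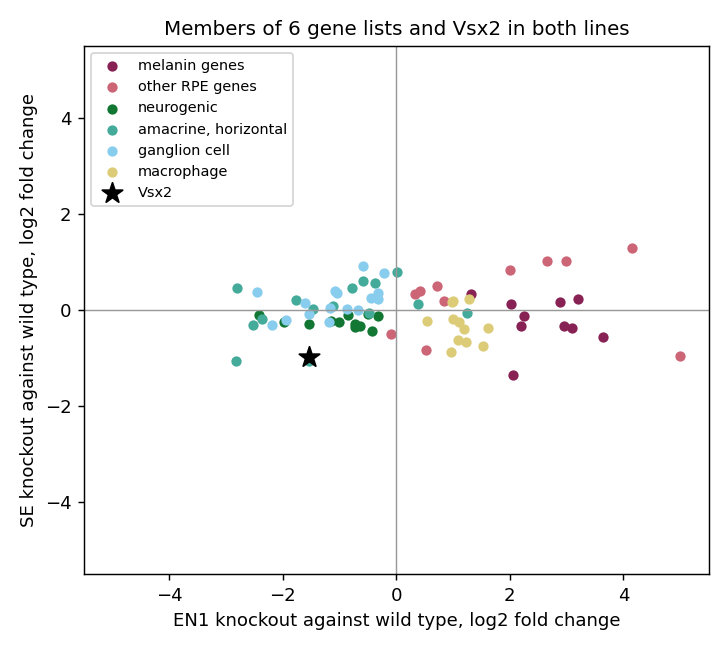
Log2 fold change in the EN1 line (horizontal) against that in the SE line (vertical) for the members of 6 gene lists, one point per gene, and for Vsx2 (star). Melanin genes spread along the horizontal axis, with medians of 2.89 in the EN1 line and -0.23 in the SE line, and Vsx2 lies at -1.55 and -0.99.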

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

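The counts over other splits of the libraries were planned; all other tests of an explanation in this part were chosen after the result was seen, as were the list tests of the difference between the lines.

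The 2 knockout effects differed for 1168 genes. Of the genes with the smallest p, the SE effect lay above the EN1 effect for Eno1b by 5.67 log2 units, Ntn1 by 3.58, Smoc1 by 3.28, Hs3st4 by 2.39 and Hkdc1 by 2.59. It lay below for Col9a2 (-2.31), Afap1l2 (-3.48), Rab27a (-3.03), Sned1 (-2.58) and Mterf4 (-1.62). By list, the median difference was above 0 for neurogenic (0.60), ganglion cell (1.22), photoreceptor (0.67), amacrine and horizontal cell (1.23), DNA replication (0.23), mitosis (0.50), hedgehog target (0.62) and hypoxia and glycolysis genes (0.22). It was below 0 for melanin (-2.95), other RPE (-0.93), ciliary margin (-1.12), lens (-4.70) and macrophage genes (-1.45). With an estimated correlation none of these lists passed (adjusted p from 0.051 to 0.408). Of 60 regroupings of the libraries, the real one included, 1 gave as many differing genes, the real one. The highest other gave 886, and it kept the EN1 genotypes as they are while mixing those of the SE line. The other drawn regroupings all mixed the EN1 genotypes and so broke up the EN1 effect itself. They therefore cannot decide whether the 2 effects differ, only whether the real groups carry an effect.

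Of 274 groups of 4 libraries 15 had a library far from the other 3, where chance flags about 1 in 20 groups, or 13.7 here. The number given is its gap divided by the range of the group. Among EN1 wild types these were Mitf in library 1 (0.861), Sncg (0.872), Gnat2 (0.948) and the progenitor list (0.935) in library 3, and Gja1 (0.838) and the photoreceptor list (0.886) in library 4. In EN1 knockout 3 they were Mlph (0.854), Gpr143 (0.833), Hspa1b (0.984), the bipolar list (0.912) and the melanin list (0.885). The others were the sex-linked list in knockout 1 (0.873), Postn (0.913) and the genes flanking Vsx2 (0.89) in knockout 2, and Eomes in knockout 4 (0.831).

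The EN1 comparison gave 3593 called genes in the real split of its 8 libraries, and 1 of the 35 splits, the real one, gave as many. The highest other split gave 0. The SE comparison gave 5 in the real split and at most 0 in the others (1 of 10 splits as large); 10 splits are too few for a share under 0.05.

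Pigment and RPE genes were higher in the EN1 knockouts, where lens, macrophage and mesenchyme transcripts were higher too. Lens tissue carried over in the dissection did not account for the rise: with a term for the lens level the median log2 fold change of the melanin genes was 3.07. The SD over these genes divided by the square root of their number was 0.29, and genes are not independent replicates. With that term the median of the lens genes went from 2.02 to -0.18. Without the 3 lens-high libraries the melanin median was 2.36, although 18 of 22 lens genes were then called higher. Other carried-over tissue stays open, since macrophage genes stayed higher with the lens term (10 of 12 called, median 1.3; 5 of 12 and 0.88 without the 3 lens-high libraries), while of the mesenchyme genes 1 of 12 was called (median 1.01). So does RPE of unchanged kind left on the knockout retinas, or an effect of the EN1 deletion on retinal cells, which these counts do not separate. The median of the melanin genes rose by 2.04 log2 units more than that of the other RPE genes. Retinal expression of the latter could produce such a gap. The mean log2 fold changes of the 2 lists, 2.69 and 1.77, lay closer together, so the size of the gap depends on the summary used.

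Neurogenic genes were lower in the EN1 knockouts. Dilution of retinal RNA alone, by cells without progenitor transcripts, would lower progenitor genes alike. The neurogenic level fell below the progenitor level by more than the spread of libraries (difference of the 2 between knockouts and wild types -0.93, SD of libraries 0.0685). The exact permutation test gave p = 0.0286, the smallest possible. Progenitor genes themselves went both ways, 4 higher and 4 lower of 16, and other cells may express some of them. Dilution beside other changes is therefore not excluded. The GC trend of the libraries did not account for it, since 10 of the 10 neurogenic genes called lower were still called lower with that trend removed. A candidate explanation is an effect of the EN1 deletion on neurogenesis, as a hypothesis from the same data. A delay of the knockout retinas in age, which would also lower these genes, was not tested.

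Genes other than Vsx2 called in the SE knockouts were Eno1b, Zfp277, Cep128 and Gm7120. Trends with transcript length and GC content did not account for these calls, since 4 of 4 stayed with either removed, although Cep128 and Gm7120 lost theirs without 1 of several libraries. Chromosome segments that differ between the knockout and wild-type mice stay open: among the 50 genes with the smallest p, chromosome 13 held 7 against 1.95 expected (adjusted p = 0.0653), with 0.00177 among the top 20 and 0.879 among the top 100, and the number 50 was chosen after these were seen. Of the called genes only Gm7120 lies there, while Zfp277 and Cep128 lie on chromosome 12 with Vsx2. Chromosome 12 held 5 of the top 50 against 1.77 expected (one-sided Fisher's exact test, p = 0.0312, adjusted p = 0.239). Those 5 include Vsx2 itself and the called genes Zfp277 and Cep128, so the excess is partly fixed by the genes in question. It cannot decide whether a differing segment lies there. Among the top 100 chromosome 12 held 5 against 3.54 expected, and chromosome 4 held 7 of the top 50 against 3.11. Segments of that kind may hold variants that change counts, and an effect of the SE deletion itself is open too, and these libraries do not separate the 2.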

How the results depend on the processing

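The length, GC, detected-gene, DESeq2 filter, lens and pairwise left-out fits were chosen after the data were examined. Among 177 results of named genes and 50 of lists, 139 and 21 kept their side of the threshold in every fit run. Direction was held to only where a result was called. Results that were never called could change sign and still count, as Xist did in the SE line (-0.46 to 0.83 without 1 library). In the SE line DESeq2 called 339 genes (176 with its mean-count filter off), no low-count filter 83, both lines in one fit 10 and a term for detected genes 8, against 5. Without 1 library it called 2 to 8, with 2 without wild type 1, 2 or 3 or knockout 2 and 8 without knockout 1. The log2 fold change of Vsx2 in the SE line was -0.98 with DESeq2's size factors, -0.99 without the robust fit and against a fold of 1.2, and -0.84 with the GC trend removed, each past the threshold no longer, and -1.04 to -0.88 without 1 library. The difference in Vsx2 between the lines passed with DESeq2 (0.64, filter on or off) and with the GC trend removed (0.61). In the EN1 line 7658 genes were called without wild types 1 and 4 and 4890 without wild types 2 and 3, against 3593. There were 1525 without the 3 lens-high libraries and 1937 with a lens term. Genes that differed between the lines numbered 761 against a fold of 1.2, 1784 with the GC trend removed and 650 to 1600 without 1 library, against 1168. Genes called in both lines, 1 here, numbered 55 with DESeq2 (35 with that filter off), 22 with no filter, 3 in one fit, 0 with DESeq2's size factors, without the robust fit, against a fold of 1.2 and with the GC trend removed, and 0 to 1 without 1 library. Lists called in the SE line, 2 here, numbered 4 with the length trend removed, 4 with the detected-gene term, 0 with an estimated correlation, 0 with fry and 3 to 7 without 1 library (5 without wild type 2, and 7 without knockout 1 or 3). With an estimated correlation 1 EN1 list was called and with fry 16, against 14. The EN1 lens list reversed to -0.18 with the lens term, which by construction removes it. The cause of the other changes was not tested. Fits that leave libraries out also have fewer libraries, but calls rose in some of them, as without EN1 wild types 1 and 4 (7658).

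Same-numbered samples correlated between -0.178 and 0.177 in the SE line, where 2 of 6 samples correlated best with their own number. In the EN1 line numbers 1 to 4 correlated at 0.319, -0.109, 0.612 and 0.339, and 4 of 8 samples correlated best with their own number. No pairing was seen in the SE line, and a partial pairing in the EN1 line stays open. With a replicate block 8 SE genes were called, and the SE fold change of Vsx2 was -0.98 (adjusted p = 0.066) with no gene called in both lines (0). The block left 4009 EN1 genes and 1162 genes of the difference. The SE neurogenic list passed with the block (adjusted p = 0.0101, against 0.0634), as did the EN1 hedgehog list (0.0177, against 0.0511), and the EN1 lens list did not (0.0679, against 0.04), nor did its gene Cryab (0.126). In the SE line 3 lens genes were called lower with the block, Cryaa (0.0227) among them. Of the 3 hedgehog targets called lower, Ptch2 lost its call with the block (0.0732), without EN1 wild type 2 (0.0534) or 3 (0.0723), without EN1 knockout 1 (0.0526) or 2 (0.0576), and with the GC trend removed (0.0696).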

Other observations

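The tests of an explanation in this part were chosen after the result was seen, and the ribosomal protein genes were picked after the data were examined.

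Cell cycle regulators of G1 went both ways in the EN1 knockouts, 3 higher and 4 lower of 10 (3 and 5 adjusted over the list alone; adjusted p = 0.755, median -0.21, mean 0.12, and a test direction downward). Ccnd1, the main D cyclin of retinal progenitors, fell from 3883 ± 479 to 2150 ± 185 CPM, while Ccnd2 went from 126.1 ± 19.5 to 449 ± 97 and the inhibitor Cdkn1c from 175.1 ± 38.7 to 624.7 ± 116. Of 9 FGF targets 4 fell (5 adjusted over the list alone; list adjusted p = 0.0781), with Spry1 at -0.77 (SE 0.117); without 1 library 2 to 5 fell. Of 5 hedgehog targets 3 fell (3 adjusted over the list alone), with Hhip from 34.1 ± 15.4 to 9.72 ± 3.35 CPM; without 1 library 2 or 3 fell. The hedgehog list missed the threshold (adjusted p = 0.0511) and passed without wild type 1, 2 or 4 or any 1 knockout (0.0131 to 0.0431). It also passed with DESeq2's size factors (0.0429) and with fry (0.0146), among other fits, but not with an estimated correlation (0.269). Of 7 bipolar cell genes Lhx4 fell by 1.82 log2 units (SE 0.17) and Vsx1, a paralog of Vsx2, rose by 1.34 (SE 0.243; not called without the 3 lens-high libraries, 0.161), the same counts adjusted over the list alone (list adjusted p = 0.0885, and 0.0287 without wild type 3).

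Endothelial genes in the EN1 knockouts were 2 higher and 2 lower of 10, the same adjusted over the list alone (adjusted p = 0.431, median 0.13, with a test direction downward). Kdr, a VEGF receptor that retinal progenitors also express, fell from 168.6 ± 7.43 to 55.0 ± 13.5 CPM, and Cldn5, a tight junction gene, fell by 1.46 log2 units (SE 0.152). Without 1 library 0 or 1 were higher and 2 lower. Immediate early and stress genes were 4 higher and 2 lower of 12, the same adjusted over the list alone (adjusted p = 0.536), with Hspa1a, a heat shock protein, at 1.84 (SE 0.389); without 1 library 2 or 3 were higher and 0 to 2 lower, and without the 3 lens-high libraries none was called (Hspa1a 0.101). Of 12 p53 targets 1 rose, the same adjusted over the list alone (adjusted p = 0.686; 0 or 1 higher and 0 or 1 lower without 1 library), of 5 surface ectoderm genes 1 rose, likewise (0.388), and of 5 red blood cell genes none (0.979). No sex-linked gene was called in either line. In the SE knockouts these lists did not pass; median, mean and test differed in sign for bipolar (0.14, -0.08, upward), hedgehog (-0.05, 0.06, upward), Wnt (-0.02, 0.04, upward), p53 (-0.05, 0.04, upward), mitosis (-0.01, 0.07, upward), DNA replication (-0.02, 0.00246, upward) and red blood cell genes (-0.01, 0.06, downward). In the difference between the lines they differed for G1 regulators (0.12, -0.16, upward), p53 targets (-0.03, 0.06, upward) and endothelium (-0.45, -0.39, upward). Sex-linked genes, though none was called, varied between EN1 libraries in mean log2 level against the wild-type mean. That level was 0.519 and 0.543 in EN1 wild types 1 and 4, and -0.488 and -0.573 in 2 and 3. EN1 knockout 1 lay at -0.914 and the other EN1 knockouts at 0.608 to 0.829. The balance of sexes between samples was not tested.

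Ribosomal protein genes lay below 0 in the SE knockouts for 73 of 78 (median log2 fold change -0.41, none called), with a median of -0.18 once the length trend was removed, and of 0.03 in the EN1 knockouts.

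A weak shared effect of both deletions was tested as a hypothesis: genes higher in the EN1 knockouts could lie above genes lower in them in the SE line too. The gap in mean log2 level was 0.106 between 1894 and 1633 genes, and 9 of the 10 splits of the 6 SE libraries gave one as large, up to 0.387. Of 3528 genes called in the EN1 line 57.7% had the same sign in the SE line. Among those at an unadjusted p under 0.05 there, 232 had the same sign and 56 the other, a surplus that 4 of the 10 splits, the real one included, reached without Vsx2 (175 in the real one, up to 268). The real grouping did not stand out in either count, and with 10 splits a small shared shift is not excluded.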
